A study of Drosophila ananassae with 48 samples.

How the data were processed

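Messenger RNA was measured by RNA sequencing in pooled whole males of Drosophila ananassae, a fruit fly. The labels name 8 strains. Of these, 4 carry the word Fast in their titles (BKK5, BKK6, BKK10 and BKK12) and 4 the word Slow (BKK13, BKK16, BKK17 and BKK18), and the series text calls 4 strains tolerant of cold and 4 sensitive to it. Flies aged 4 to 6 days and reared at 22 °C were held at 0 °C for 3 h and sampled before the cold shock and after 15 and 90 min of recovery at 22 °C. Each strain and time has 2 libraries, which makes 48 libraries in 6 groups of 8. Per the labels' protocols, RNA was extracted without a DNase step and enriched for poly(A) before library construction.

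The deposited table holds raw counts per gene, as whole numbers that sum to different totals in each library, for 14365 genes with FlyBase identifiers. Of these, 115 had no count in any library. FastQC 0.11.5 and DESeq2 1.16.1 are named in the submitters' processing notes. The aligner, the counting program, its strand setting, the genome build and the annotation are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies therefore cannot be assigned with certainty. The files do not pair the FlyBase identifiers with gene names, and the reference table of gene symbols supplied alongside shares no identifier with them. Genes are therefore given by identifier, at most 2 higher and 2 lower per comparison. The lists of stress, metabolic, immune and tissue marker genes fixed before the data were examined were void for this reason and were not tested.

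Column names give the strain, the time and a number from 1 to 3. The labels number the 2 libraries of a strain and time 1 and 2, so a column could be tied to its group, strain and time but not to a single labelled sample. The labels do not say whether the 2 libraries came from separate vials. Where libraries rather than strains are compared, p-values measure only the spread between these libraries, which may be technical. No 2 libraries of one strain and time agreed within sampling noise (chi-square per degree of freedom from 14.4 to 193.5 over 24 pairs), and none were merged as duplicates.

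In the present work the 2 libraries of each strain and time were summed, which gave 24 sums, so that strains are the replicates. Counts were scaled by TMM and genes were kept by filterByExpr with a minimum count of 10. Responses to cold were tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest), with strain as a block and a term for each combination of phenotype and time. Fast and slow strains were compared at each time on 4 against 4 strain sums, and over all times on the 6 libraries of each strain summed. A further F test on the 48 separate libraries asked whether strains of one phenotype differed in their response. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and its quasi-likelihood F statistic. CPM values given per group are means over strains of the mean of each strain's libraries, with TMM scaling.

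The rule for named genes was written before the data were examined. For responses it takes genes past the adjusted threshold, with a mean log2 CPM of at least 1 and a change of the same sign in all 8 strains, ordered by fold change. For fast against slow and for differences in response it takes genes past the threshold with a mean log2 CPM of at least 1, ordered by fold change, and where none passes the 5 lowest p. The rule asked for 10 genes per direction, for informative product names in the responses, and for members of the gene lists. The number was lowered to 2 per direction, with the lowest p of each sign where none passed, and the other parts fell away, because no names could be paired.

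Alternatives fixed before the data were examined were other scalings (RLE size factors and library size alone), other filters, DESeq2 1.42.0, libraries kept separate with and without a replicate block, limma 3.58.1 voom with strain as a random effect, a minimum log2 fold change of 1, and leaving out each strain, each library and each replicate number. Thinning of all libraries to the smallest total, BKK17 and BKK18 as 1 strain, leaving out the deepest libraries, leave-outs for the F test, and the count of differing 15 min responses at an unadjusted p were added after the data were seen. The same models were tested on simulated counts with 200 changed genes of a mean log2 CPM of at least 1, drawn with the real means and library sizes. For 90 min against before, 97.0% of 1.5-fold and 99.0% of 2-fold changes were recovered among 13923 genes. For the difference in the 90 min response between phenotypes, 92.0% of 1.5-fold changes were recovered. For fast against slow before the shock, 76.0% of 2-fold and 97.0% of 4-fold changes were recovered among 13716 genes, and 13 of 186 calls were false (6.99%). Genes were drawn independently there, around a mean common to all strains, so likeness between particular strains was absent. With 200 changed genes the adjusted threshold is also easier to reach than where few genes differ. Recovery in the real data may therefore be lower.

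The 15 and 90 min comparisons share the untreated libraries. Their overlap is given beside 20 simulated data sets without any time effect, beside the overlap of independent lists, and with the untreated libraries split between the comparisons.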

Results

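The data comprise 48 RNA sequencing libraries from pooled whole males of 8 Drosophila ananassae strains, 4 fast and 4 slow, before a cold shock of 3 h at 0 °C and 15 and 90 min into recovery at 22 °C. The design asks how transcript levels change after the cold shock and whether strains of differing cold tolerance differ in expression or in this change. No unshocked flies were sampled at the later times. The change is called a response to cold here, but effects of elapsed time, handling or sampling cannot be told apart from it. Total counts per library, in M (mega) counts, ranged from 23.2 M to 85.6 M, with a median of 36.1 M. The 3 deepest libraries, between 77.7 M and 85.6 M, all belonged to the slow strain BKK18, and the remaining 45 reached at most 47.6 M. Mean depth was 33.5 ± 3.43 M (SD, n = 8 libraries) in untreated fast and 45.5 ± 16.6 M in untreated slow strains. The 10 most abundant genes took 5.74% to 7.80% of the counts.

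Strain was the main source of variation in expression. Of the sum of squares of log2 CPM over 13648 genes, 64.1% lay between strains, 15.2% between times, 7.23% in the combination of strain and time, and 13.4% between the 2 libraries of a strain and time. The combination of strain and time had 14 degrees of freedom and the libraries 24. Per degree of freedom, the share of that combination did not exceed the share between libraries. The contrast of fast and slow strains held 14.4% of the total. In the mean profiles of the 8 strains it held 22.5% of the variance between strains, where any contrast of 4 against 4 would hold 14.3% on average, and 3 of the 35 splits of the strains held as much (exact permutation p = 0.0857). The first principal component placed BKK16, BKK17 and BKK18 apart from the other 5 strains, among them the slow strain BKK13. BKK17 and BKK18 had the smallest distance of the 28 strain pairs, a root mean square difference of 0.20 in log2 CPM. BKK16 lay at 0.39 from BKK17 and at 0.41 from BKK18, and the remaining 25 pairs lay between 0.52 and 0.57. In a model of strain and time with libraries as units, 72 genes differed at least 2-fold between BKK17 and BKK18 (edgeR, adjusted p under 0.05), against 686 to 873 genes in those 25 pairs.

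**Figure D1:**
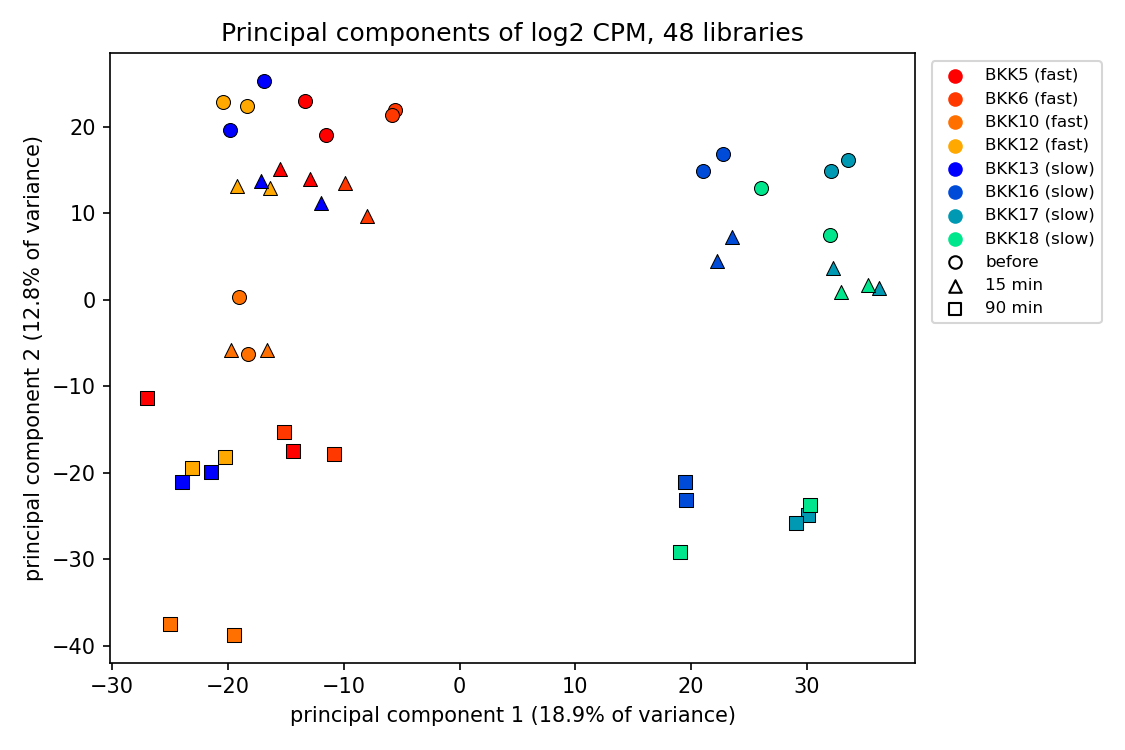
First and second principal components of log2 CPM for the 48 libraries, with colour for strain and marker shape for time. The 18 libraries of BKK16, BKK17 and BKK18 lie between 19.0 and 36.2 on the first component and the other 30 libraries between -27.0 and -5.54, while 90 min libraries lie lower on the second component than untreated libraries of the same strain.

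**Figure D2:**
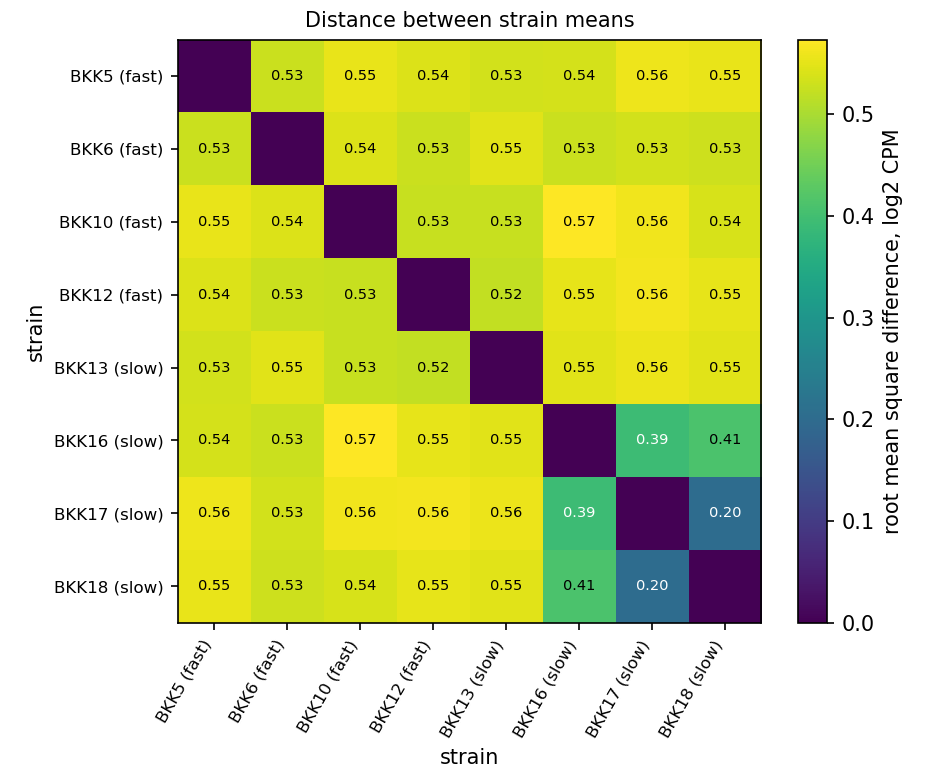
Root mean square difference in log2 CPM between the mean profiles of each pair of strains, over the 6 libraries of each strain. The pair BKK17 and BKK18 has the lowest value, 0.20, and the pairs not formed among BKK16, BKK17 and BKK18 lie between 0.52 and 0.57.

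At 15 min after the cold shock the 2 genes with the largest rise under the rule for named genes had risen from under 1 CPM. FBgn0095402 rose from 0.0879 ± 0.0628 to 12.4 ± 5.80 CPM (mean ± SD, n = 8 strains), a log2 fold change of 7.14 ± 0.28 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.00e-11). Its untreated level rests on 52 counts over 16 libraries, of which 2 had none. FBgn0093652 rose from 0.490 ± 0.334 to 51.4 ± 18.4 CPM, a log2 fold change of 6.85 ± 0.17 (edgeR adjusted p = 2.31e-14). FBgn0274843 fell by 1.32 on the log2 scale, from 12.4 ± 8.10 to 4.63 ± 3.24 CPM, and FBgn0094287 fell by 1.31, from 25.8 ± 12.1 to 9.94 ± 4.70 CPM (edgeR adjusted p = 0.000630 and 0.000371). The rule required each of these 4 genes to change in the same direction in all 8 strains, so that likeness is no separate evidence. The largest fall of any called gene, in a gene outside the rule, was -3.73 on the log2 scale. In BKK18 the fall of FBgn0274843 rested on the untreated library numbered 2, with 21.2 CPM. The untreated library numbered 3 had 1.66 CPM, and the 15 min libraries had 1.70 and 2.25 CPM. In BKK13 the untreated library numbered 2, with 3.66 CPM, lay below both 15 min libraries. Untreated and 15 min libraries also overlapped in BKK12 and BKK17, but not in BKK5, BKK6, BKK10 or BKK16. For FBgn0094287 they overlapped in BKK18 alone. There the untreated library numbered 3 had 4.85 CPM and the 15 min libraries had 3.15 and 8.30 CPM. The 24 genes that rose at least 2-fold, of which 7 stood under 1 CPM before the shock, went from 0.0442 ± 0.00480% to 0.318 ± 0.0209% of all counts (n = 8 strains).

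In all, 2371 of 13923 genes changed at 15 min, 1128 higher and 1243 lower, and most changes were small: the median log2 fold change was 0.19 among genes that rose and -0.15 among those that fell, and only 24 genes rose and 6 fell at least 2-fold. Scaled by library size alone, 882 genes were higher and 1558 lower, and with DESeq2 1306 higher and 1290 lower. Higher genes also outnumbered lower ones without BKK10, without the 15 min libraries numbered 3 of BKK5, 1 of BKK17 or 3 of BKK18, without the 90 min library numbered 3 of BKK16, and with the lower-numbered libraries alone. The count fell to 1149 without the 90 min library numbered 1 of BKK5, to 1497 without the untreated library numbered 3 of BKK18, to between 1393 and 1555 without BKK12, BKK13, BKK17 or BKK18, to 956 when only the lower-numbered and to 293 when only the higher-numbered library of each strain and time was kept, where the falls of FBgn0274843 and FBgn0094287 no longer passed the threshold (edgeR adjusted p = 0.124 and 0.123).

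After 90 min the response was broader and larger. FBgn0095402 reached 22.0 ± 6.69 CPM and FBgn0093652 reached 89.2 ± 36.7 CPM (n = 8 strains), log2 fold changes of 8.07 ± 0.27 and 7.63 ± 0.17 against before (edgeR adjusted p = 4.02e-13 and 1.86e-15). FBgn0090572 fell by 2.56 ± 0.32 on the log2 scale, from 10.3 ± 6.60 to 1.58 ± 0.313 CPM, and FBgn0093580 fell by 2.31 ± 0.17, from 70.8 ± 53.4 to 13.2 ± 6.83 CPM (edgeR adjusted p = 5.11e-06 and 9.50e-09). The rule again required the same sign in all 8 strains. In BKK12 the fall of FBgn0090572 was only from 1.98 to 1.81 CPM, a log2 change of -0.18. Its untreated library numbered 1, with 0.749 CPM, lay below both 90 min libraries (1.23 and 2.38 CPM). The other strains had log2 changes from -1.18 in BKK13 to -3.94 in BKK17. At 15 min FBgn0090572 still stood at 13.6 ± 4.09 CPM and FBgn0093580 at 58.4 ± 45.6 CPM. The 206 genes that rose at least 2-fold took 0.865 ± 0.132% of all counts before the shock, 1.26 ± 0.102% at 15 min and 3.41 ± 0.346% at 90 min. Of them, 39 stood under 1 CPM before the shock and 197 were higher in each of the 8 strains. The 66 genes that fell at least 2-fold went from 0.284 ± 0.0278% to 0.112 ± 0.0129% of all counts. Among them, a gene outside the rule for named genes had the largest fall, -3.56 on the log2 scale.

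A total of 5824 genes changed at 90 min, 2612 higher and 3212 lower, which is 41.8% of those tested. Scaled by library size alone, the split was 1858 higher and 4481 lower, whereas it was 2651 and 2455 with libraries kept separate and 2897 and 2831 without the 15 min library numbered 1 of BKK17. Fold changes correlated more strongly between strains than at 15 min: across genes, the correlation between the fold changes of 2 strains had a median of 0.654 over 28 strain pairs at 90 min and of 0.348 at 15 min, where genes are not independent replicates. Of all 13923 genes tested, 25.4% had the same sign in all 8 strains at 90 min and 8.15% at 15 min, where strains without any effect that vary independently would give 0.781%. Changes were also larger at 90 min, and neither measure was corrected for noise between libraries. These values alone therefore cannot tell whether the strains' responses were more alike.

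**Figure D3:**
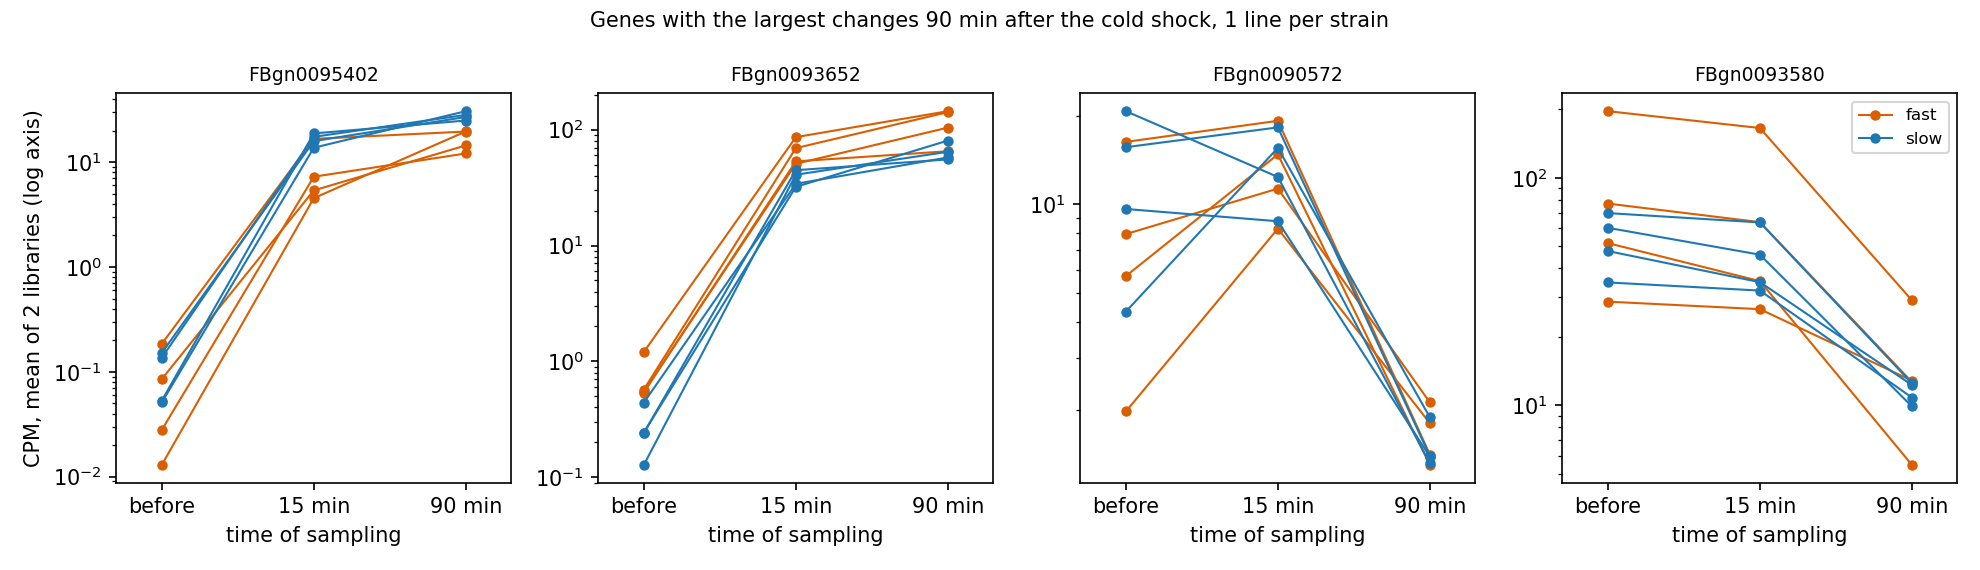
CPM of the 2 genes with the largest rise and the 2 with the largest fall 90 min after the cold shock, among called genes with a mean log2 CPM of at least 1 and the same sign in all 8 strains, on a log axis, with 1 line per strain (mean of 2 libraries), fast strains in orange and slow strains in blue. FBgn0095402 and FBgn0093652 are higher at 15 min than before in all 8 strains, and FBgn0090572 and FBgn0093580 are lowest at 90 min in all 8 strains. The selection required a 90 min change of one sign in every strain. In BKK12 that of FBgn0090572 is only from 1.98 to 1.81 CPM.

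Between 15 and 90 min, 2360 genes rose and 2718 fell, or 1973 and 3810 scaled by library size alone (edgeR, 13923 genes). The split was 2593 higher and 2127 lower with libraries kept separate, 2499 and 2310 without the 15 min library numbered 1 of BKK17, and 1902 and 1740 with the higher-numbered libraries alone. Genes called at 15 min took several courses. Of the 1128 genes that had risen, 570 were also higher at 90 min than before, 461 were not called at 90 min and 97 were lower. Of the 1243 that had fallen, 729 were also lower at 90 min, 347 were not called and 167 were higher. From 15 to 90 min, 368 of the genes that had risen fell again and 191 rose further, while 410 of those that had fallen rose again and 269 fell further. Both steps use the same 15 min libraries, so picking genes by their 15 min change favours a move back. How many would move back by this selection alone was not tested. Of the genes higher at 90 min, 71.8% had not been called at 15 min, and of those lower, 74.3%.

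Both comparisons share the untreated libraries. Simulated data without a time effect gave at most 1 gene higher and none lower in both. The simulated lists themselves held at most 1 gene per direction at either time, so their overlap had to be this small. Independent lists of the observed sizes would share 212 higher and 287 lower genes. With the lower-numbered untreated libraries used for 15 min and the others for 90 min, 1267 genes were called at 15 min and 5444 at 90 min. Of these, 247 were higher and 305 lower at both times, where independent lists of these sizes would share 108.7 and 139.9. With the opposite assignment 2163 and 4565 genes were called, with 246 higher and 508 lower at both times, where independent lists would share 153.6 and 202.6. The covariance of the log2 fold changes across genes was 0.0423, against 0.00376 in the simulations, and 0.0357 and 0.0339 with the untreated libraries split. The correlation across genes was 0.533 (Spearman 0.367), against a mean of 0.482 (Spearman 0.453) in the simulations.

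Taken separately, the fast strains had 191 genes changed at 15 min, 68 of them lower and the others higher, and the slow strains 2683, 1359 higher and 1324 lower. At 90 min the fast strains had 3564, 1773 higher and 1791 lower, and the slow strains 4836, 2175 higher and 2661 lower. Of the 191 genes in fast strains, 150 were also called in slow strains, all in the same direction, and at 90 min 2853 genes were called in both, 2844 of them in the same direction; independent lists would share 36.8 and 1238 genes. Scaled by library size alone, the split in fast strains was 121 higher and 124 lower at 15 min and 1325 higher and 3475 lower at 90 min. The count for slow strains at 15 min was unstable: it was 888 without BKK18, 941 without BKK13 and 1333 without BKK17, and 857 without the 90 min library numbered 1 of BKK5, 1083 without the untreated library numbered 3 of BKK18, 1668 without the 90 min library numbered 2 of BKK18 and 1698 without the 15 min library numbered 2 of BKK13. The count for fast strains at 15 min was 67 without BKK10 and 81 without BKK12. Without the untreated library numbered 3 and the 90 min library numbered 2 of BKK18, the counts at 15 min were 97 in fast and 515 in slow strains. All strains share 1 estimate of the spread in this fit.

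A difference in response between fast and slow strains was tested directly. At 90 min, 2 genes passed (edgeR quasi-likelihood, Benjamini-Hochberg). FBgn0090720 fell less in fast strains, with a log2 fold change of -0.72 against -1.49 in slow strains, a difference of 0.76 ± 0.12 (SE, adjusted p = 0.0444), and it was lower at 90 min than before in all 8 strains. FBgn0089855 rose from 91.9 ± 8.11 to 123.9 ± 12.95 CPM in fast strains (SD, n = 4) and stood at 90.6 ± 9.17 and 93.4 ± 11.1 CPM in slow strains, a difference of 0.39 ± 0.05 (adjusted p = 0.0193). Scaled by library size alone, 1 gene was higher and 1 lower in this test, and with RLE size factors 1 passed. With DESeq2 49 genes passed, and with all libraries thinned to one depth none did (adjusted p = 0.0752 and 0.0624 for the 2 genes by edgeR). Over 67 alternatives the call of FBgn0090720 was lost in 40 and that of FBgn0089855 in 16 (edgeR adjusted p up to 0.700 and 0.721), with the sign kept in each. The count differed by over 1.5 times in 31 of the 48 fits without a single library, between 0 and 13.

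At 15 min no gene passed with edgeR on strain sums, where 1943 of 13923 genes had an unadjusted p under 0.05, and 86 passed with DESeq2. The genes with the lowest p of each sign did not pass in this fit. FBgn0099889 had a log2 fold change of 0.00 in fast and -0.40 in slow strains (difference 0.40 ± 0.06, edgeR adjusted p = 0.0914), and FBgn0096824 one of -0.02 in fast and 0.37 in slow strains (difference -0.39 ± 0.07, edgeR adjusted p = 0.117). Of 67 alternatives, FBgn0099889 passed in 10, among them DESeq2 (adjusted p = 1.91e-05), and FBgn0096824 in 5, all of them edgeR fits without 1 strain or library (adjusted p from 0.00957 to 0.0499). The 10 also include edgeR with libraries kept separate and a replicate block (adjusted p = 0.0175). Without BKK12, 131 genes passed, and without BKK10, 3. Without the untreated library numbered 2 of BKK12, 48 passed, and 1 to 9 passed without the 15 min library numbered 2 of BKK12, 1 of BKK6, 2 or 3 of BKK16, the untreated library numbered 2 of BKK13 or its 90 min library numbered 3. The 206 genes induced at least 2-fold at 90 min took 3.54 ± 0.295% of counts in fast and 3.27 ± 0.381% in slow strains at 90 min (SD, n = 4 and 4; two-sided exact permutation p = 0.343, adjusted over 3 times 0.343).

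Few genes separated fast from slow strains as groups. FBgn0097954 was higher in fast strains at each time, with 37.0 ± 3.83 against 8.10 ± 0.851 CPM before the shock (SD, n = 4 strains each). Its log2 difference was 2.20 ± 0.12 before, 2.27 ± 0.11 at 15 min, 2.37 ± 0.11 at 90 min and 2.29 ± 0.11 over all times (SE; edgeR adjusted p = 0.000291, 9.55e-05, 8.75e-05 and 0.000103), and it was not called at 15 or 90 min against before (edgeR adjusted p = 0.700 and 0.877). FBgn0089751 was higher in fast strains at 15 min, with 12.3 ± 5.49 against 0.814 ± 0.210 CPM, a log2 difference of 3.91 ± 0.39 (edgeR adjusted p = 0.0149), and over all times, 3.37 ± 0.36 (edgeR adjusted p = 0.0372). FBgn0100333 was lower in fast strains at 15 min, with 5.83 ± 0.646 against 16.03 ± 1.34 CPM, a log2 difference of -1.46 ± 0.11 (edgeR adjusted p = 0.00372), and over all times, -1.32 ± 0.13 (edgeR adjusted p = 0.0347). Neither difference was particular to 15 min. Before and at 90 min it was 3.54 and 2.78 for FBgn0089751 (edgeR adjusted p = 0.0680 and 0.0878). For FBgn0100333 it was -1.25 and -1.29 (edgeR adjusted p = 0.0896 and 0.0954). Neither gene passed for the 15 min difference in response (edgeR adjusted p = 0.376 and 0.286) or for the 90 min one (0.225 and 0.928). At 90 min against before, FBgn0089751 was called lower in fast strains (log2 -0.38, edgeR adjusted p = 0.00890) and higher in slow strains (0.37, 0.0415). FBgn0100333 was called higher over all strains at 15 and 90 min, by 0.15 and 0.12 (edgeR adjusted p = 0.0335 and 0.0332). Another called gene, not named because identifiers are limited to 2 per direction, was higher in fast strains by 1.05 at 15 min and by 0.88 over all times on the log2 scale.

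**Figure D4:**
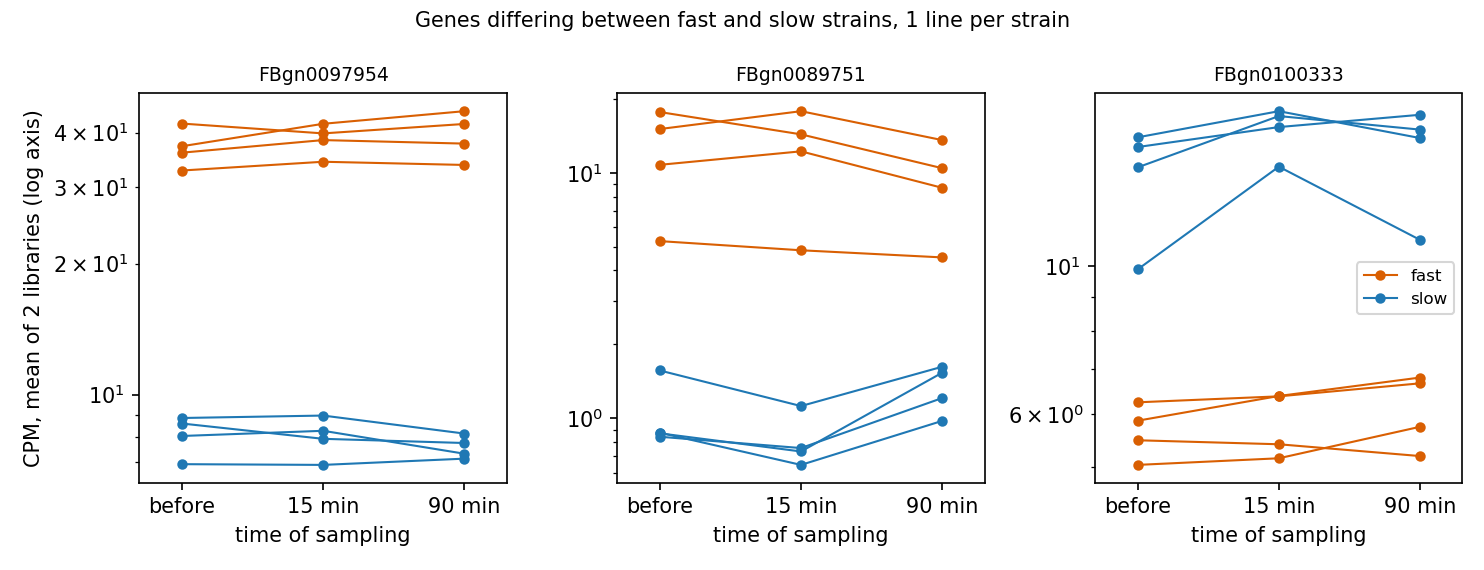
CPM of 3 genes that differed between fast and slow strains, on a log axis, with 1 line per strain (mean of 2 libraries), fast strains in orange and slow strains in blue. FBgn0097954 stands between 32.7 and 44.8 CPM in fast strains and between 6.90 and 8.95 CPM in slow strains at the 3 times.

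With strains as replicates, 1 gene differed between fast and slow strains before the shock, 4 at 15 min, 1 at 90 min and 4 over all times (edgeR, 13712 to 14044 genes tested). DESeq2 called 184, 298, 150 and 231 genes on the same sums. Without BKK13, the slow strain outside the group of BKK16, BKK17 and BKK18, edgeR called 30, 195, 86 and 69 genes. Treating BKK17 and BKK18 as 1 strain left 1, 2, 1 and 1 genes. The call of FBgn0097954 held in each alternative tried, whereas that of FBgn0089751 was lost over all times without BKK5, BKK10, BKK12, BKK16, BKK17 or BKK18 (edgeR adjusted p from 0.0592 to 0.219), without the 15 min library numbered 2 of BKK13 (0.0502), with the lower-numbered libraries alone (0.0669) and with BKK17 and BKK18 as 1 strain (0.219). At 15 min it was lost without BKK10, BKK16, BKK17 or BKK18 (edgeR adjusted p from 0.0503 to 0.132) and with that merge (0.123). That of FBgn0100333 over all times was lost without BKK5, BKK6, BKK10, BKK12, BKK17 or BKK18 (edgeR adjusted p from 0.0592 to 0.143) and with the merge (0.208). Single libraries moved these counts too: before the shock there were 2, 7 and 3 genes without the libraries numbered 1 of BKK6, 2 of BKK13 and 2 of BKK16, at 15 min 8 and 9 without number 2 of BKK12 and 3 of BKK13, at 90 min 2 without number 1 of BKK6 or of BKK12, and over all times 2 without the 15 min library numbered 2 of BKK13.

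The response was also compared between strains of one phenotype. This test measures only the spread between the 2 libraries of a strain and time, which may be technical. Differences between vials or in sampling therefore cannot be told apart from differences between strains. With the 48 libraries kept separate, 33 of 13641 genes had a response that differed between strains of the same phenotype (edgeR F test with 12 terms). The count was 7 without BKK13, 11 without BKK10 and 18 without BKK17, and it differed by over 1.5 times in 28 of the 48 fits without a single library, between 11 and 54.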

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

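No test in this part was chosen after its result was seen. A gap between the most extreme library and its nearest neighbour, beyond Dixon's 95% critical value for 8 values, was found in 10 of 96 sets of 8 libraries, formed by 3 library measures and 13 named genes in 6 groups. Chance gives about 1 in 20, or 4.8 sets, for independent values. Each set holds 2 libraries of each of 4 strains, which are not independent, so the number expected here is not known.

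The untreated library numbered 3 of BKK18 stood apart in depth with 85.6 M counts. Of FBgn0093652, the library numbered 1 of BKK6 was the highest of the fast libraries both before the shock, with 1.63 CPM, and at 15 min, with 109.7 CPM, and the 90 min library numbered 3 of BKK16 was the highest of the slow libraries, with 95.01 CPM. Of FBgn0274843, the 15 min library numbered 1 of BKK12 had 16.01 CPM and the 90 min library numbered 3 of BKK13 had 9.996 CPM, each the highest of its group. The untreated library numbered 2 of BKK13 had 54.7 CPM of FBgn0094287. The 15 min library numbered 3 of BKK13 had 1.40 CPM of FBgn0089751 and 80.5 CPM of FBgn0099889, and its 90 min library numbered 3 had 85.8 CPM of FBgn0099889. Of these 10 values, 5 come from BKK13, and no explanation was tested.

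The 90 min response differed between fast and slow strains for FBgn0090720 by 0.76 on the log2 scale (-0.72 in fast and -1.49 in slow strains) and for FBgn0089855 by 0.39 (0.42 in fast and 0.03 in slow strains), by a direct test of the difference with edgeR (adjusted p = 0.0444 and 0.0193). Both genes were flagged because they passed this same test, so it adds no further evidence. Their calls were lost in 40 and 16 of 67 alternatives.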

How the results depend on the processing

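Tests added after the data were seen were the thinning, BKK17 and BKK18 as 1 strain, the deepest libraries left out, the count at an unadjusted p, and the strain and library leave-outs of the F test. Of 849 alternative counts, 665 stayed within 1.5 times the main count and 184 did not. No named gene changed sign in 1180 alternative values, and the calls of the genes named for 15 and 90 min against before held in 526 of 528. The tests of gene lists, with their alternatives, were not run because identifiers could not be paired with names. The cause of each shift below was not tested, except that a minimum fold change lowers a count by its construction.

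A minimum log2 fold change of 1 left 30 genes at 15 min, 272 at 90 min, 231 between 15 and 90 min, 23 and 279 in fast and 43 and 298 in slow strains at 15 and 90 min, and 0 for the 90 min difference in response. DESeq2 called 389 genes in fast strains at 15 min, 86 and 49 for the differences in response at 15 and 90 min, and 184, 298, 150 and 231 for fast against slow before, at 15 min, at 90 min and over all times. For fast against slow in that order, limma voom with strain as a random effect called 47, 102, 57 and 533 genes, and libraries kept separate without a block 612, 1346, 446 and 4394. For responses, libraries kept separate without a replicate block still had strain as a block. They gave 1493 genes at 15 min, 1124 in slow strains at 15 min, and 2 and 11 for the differences in response. RLE size factors left 1 gene for the 90 min difference in response, where library size alone gave 1 higher and 1 lower. A mean CPM of at least 1 gave 7 genes between fast and slow strains at 15 min. Thinning to 23214649 counts per library gave 0 genes for the 90 min difference in response and 2 for fast against slow before the shock. BKK17 and BKK18 as 1 strain gave 1 gene for the 90 min difference, 2 for fast against slow at 15 min and 1 over all times. Without 2 of the 3 deepest libraries, 97 genes were called in fast and 515 in slow strains at 15 min. Splitting the untreated libraries left 552 and 754 genes shared between 15 and 90 min, against 1299, from shorter lists of 1267 and 2163 genes at 15 min and 5444 and 4565 at 90 min.

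The replicate numbers in the files were not taken to pair the libraries, since not every correlation between times of the difference between a strain's 2 libraries was over 0.1. Of 24, 16 were, among them all those of BKK10, BKK12 and BKK13, with a median of 0.137 and a range from -0.0716 to 0.417, which leaves pairing within some strains open. With the replicate block, 344 genes were called in fast strains at 15 min, 5 and 14 for the differences in response at 15 and 90 min, 546, 1129, 385 and 4407 for fast against slow before, at 15 min, at 90 min and over all times, and 58 by the F test. The block also brought FBgn0099889 past the threshold for the 15 min difference (edgeR adjusted p = 0.0175). For responses and the F test the block was each combination of strain and replicate number. For fast against slow it was only a term for the lower- or higher-numbered library, with libraries as replicates.

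Leaving out single strains, libraries or replicate numbers gave 293 to 2613 genes at 15 min, 3745 to 6049 at 90 min, 47 to 271 and 1911 to 3707 in fast strains at 15 and 90 min, 160 to 3175 and 2678 to 5391 in slow strains, 0 to 131 and 0 to 37 for the differences in response, 1 to 30, 2 to 195, 1 to 86 and 1 to 69 for fast against slow, and 7 to 54 for the F test. Keeping 1 replicate number leaves 1 library per strain and time, and the lowest counts at 15 min, 293, 160 and 47, came from leaving out the lower-numbered libraries. After thinning to the depth of the shallowest library, 1811 genes were called at 15 min and 5307 at 90 min.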

Other observations

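Of the tests below, those set down after their results had been seen are the slopes at 15 and 90 min, the depth and single-strain tests of the 15 min counts, the count at an unadjusted p, the splits of the strains for fast against slow and for the differences in response with strains as replicates, shared ancestry, and the sorting of splits by whether they keep BKK16, BKK17 and BKK18 together.

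Whether genes that differ between untreated fast and slow strains are more often cold-responsive was tested against other groupings of the strains. Of the 1169 genes with an unadjusted p under 0.05 between fast and slow strains before the shock, 45.7% were called at 90 min, against 41.98% of the others, a ratio of 1.09. Of the 35 splits of the 8 strains, 13 gave as high a ratio, the highest other being 1.23. Untreated fast strains did not lie further along the 90 min response of the other strains by a margin that passed: the slope of a strain's untreated deviation on that response averaged 0.0705 ± 0.107 in fast and -0.0133 ± 0.0451 in slow strains (SD, n = 4 each; two-sided exact permutation p = 0.2, adjusted over 4 tests 0.2). BKK10 alone had a slope of 0.222. The slope of each strain's 90 min response on that of the others averaged 0.914 ± 0.0684 in fast and 0.975 ± 0.0584 in slow strains (two-sided exact permutation p = 0.2), and the slope at 15 min over genes with a log2 change beyond 0.5 in the other strains gave a two-sided exact permutation p of 0.143. For the untreated slope and the share of cold-responsive genes, the bounds set beforehand for dropping the hypothesis, p of at least 0.05 and at least 5% of splits, were met. Both are left open, a decision taken after the values were seen, because with 4 strains against 4 a missed threshold does not exclude a difference.

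BKK17 and BKK18 were close in expression, with BKK16 near them. Libraries of 1 strain under both names are argued against by the 72 genes that differed at least 2-fold between them, above a bound of 50 set beforehand, though separately reared flies of one stock were not tested. Greater depth of BKK18 is argued against, since after thinning to one depth their distance was 0.388 of the median of the other pairs. Shared ancestry may account for the closeness but was not tested: the distance, 0.203, does not measure it.

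With libraries rather than strains as replicates, 4394 genes differed between fast and slow strains over all times, against 4 with strains. The other 34 splits of the strains gave 1134 to 6044 genes, with a median of 0.482 of the real count, just under the bound of 0.5 set beforehand for dropping the dependence of libraries of one strain as an explanation. Libraries of one strain were not independent, with a correlation of 0.504 by limma over all times. Neither that fit nor the one with 4394 genes held a term for time. Differences between times therefore count as spread within a strain there, and 0.504 is not the correlation of libraries of one strain and time. Each of the other splits gave at least 1134 genes with libraries as replicates, against at most 4 with strains. How much of the real count this dependence accounts for is left open. That decision was taken after the value was seen, because the quartiles of 0.397 and 0.764 span that bound. A difference between fast and slow strains as groups met its bound for dropping it as well, with 6 of 35 splits giving as many genes, but cannot be told apart from the closeness of 3 slow strains. The 4 other splits that keep BKK16, BKK17 and BKK18 together had a median of 5535 genes and the splits that part them 2032, so these splits are no neutral background, a reason also found after the values were seen.

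Fewer genes were called at 15 min in fast than in slow strains, 191 against 2683. But the test of the difference itself passed for no gene with edgeR on strain sums, and for 86 with DESeq2. It passed for 2 with libraries kept separate without a replicate block and for up to 131 with 1 strain or library left out. With the replicate block it also passed for some genes, among them FBgn0099889. Lower depth of the fast libraries is argued against by thinning, after which the slow count was 9.16 times the fast count, and a single slow strain by the lowest count with 1 slow strain left out, 888. A smaller response of fast strains over all genes may contribute: the slope of each strain's 15 min response on that of the others averaged 0.761 ± 0.111 in fast and 0.945 ± 0.0952 in slow strains (SD, n = 4 each; two-sided exact permutation p = 0.0571, adjusted over 4 tests 0.2, where 0.0286 is the smallest the design allows). At an unadjusted p under 0.05, 1943 genes had a differing 15 min response, and 2 of the 35 splits gave as many, the highest other 2483. These values leave a smaller 15 min response of fast strains as an open hypothesis.

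Chance assignment of times was excluded for 15 min against before (1 of 100 splits gave as many genes as the real 2371, highest other 1376), 90 min against before (1 of 100, real 5824, highest other 3705) and 90 against 15 min (1 of 100, real 5078, highest other 3138). Within 4 strains only 8 splits exist, too few for a share under 0.05: the real counts and the highest others were 191 and 1 in fast strains at 15 min, 3564 and 15 at 90 min, 2683 and 0 in slow strains at 15 min, and 4836 and 2 at 90 min. Of the 35 splits into 4 and 4 strains, 1 gave as many genes as the real 4 between fast and slow strains at 15 min (highest other 2). That is the smallest share these splits allow, it is not adjusted for the other comparisons, and at an unadjusted p under 0.05 the 4 other splits that keep BKK16, BKK17 and BKK18 together gave 1660, 2056, 2166 and 2212 genes against the real 1845, so it is weak evidence against chance. Chance was not excluded before the shock (9 splits, real 1, highest other 5), at 90 min (8 splits, real 1, highest other 5), over all times (3 splits, real 4, highest other 4) or for the 90 min difference in response (6 splits, real 2, highest other 13). For the 15 min difference the real count is 0, which every one of the 35 splits matches, so this comparison decides nothing. The highest other split called 168 genes, with BKK5, BKK6, BKK10 and BKK16 on one side, and the remaining 33 at most 1. Why this split gave so many more genes than the real one was not tested.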
